A study of Drosophila melanogaster with 4 samples.

How the data were processed

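Chromatin immunoprecipitation followed by sequencing was carried out on wild-type Oregon-R larvae of Drosophila melanogaster in the 3rd instar. The antibody was a rabbit polyclonal raised against residues 1 to 150 of POF, an RNA-binding protein known for coating chromosome 4. Of the 4 samples, 2 are POF ChIP libraries and 2 are input libraries, each numbered 1 and 2 in the titles. Per the labels' protocols, homogenized larvae were crosslinked with formaldehyde, chromatin was released with detergent and sonication, and it was precipitated with antibody and protein A beads. The groups were taken from the titles. The description of ChIP replicate 2 reads only as input DNA and that of input replicate 1 names the POF antibody, whereas the titles and source names say otherwise, and the titles were followed. No label says whether the replicates came from separate cultures of larvae, so the spread between them may be technical.

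The analysis started from 3 lists of enriched clusters, 1 for each ChIP library and 1 combined list for the replicate set. Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. Coordinates are those of FlyBase release 5, per the file headers, which also give the sequence lengths used here. The enrichment caller, its threshold, the input library each list was called against, and whether reads were pooled or lists were merged for the combined list are not given in the sources used here. Each cluster carries 1 score from the authors, taken here as log2 from its values, with no stated reference. The base was tested on the values. In replicate 1, 90.8% of 6241 scores differed from the list's most frequent score by the base 2 logarithm of a ratio of whole numbers with a denominator of at most 200 (relative tolerance 1e-09), and no score did so for base e. The figures for base 2 were 47.1% of 20052 scores in the combined list and 31.1% of 5758 in replicate 2. Scores were used to rank, filter and describe clusters within 1 list, and the scores of overlapping replicate clusters were correlated. The lists hold no read counts, so the depth per library is unknown and no interval that needs a depth is given. No list of the input libraries was analysed here. The combined list also holds 1 region called depleted, which was left out of the clusters.

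Clusters on the 6 assembled chromosome arms (2L, 2R, 3L, 3R, 4 and X) entered the comparisons. The covered share is the percentage of a chromosome's bases inside clusters. The number of clusters on chromosome 4 was compared with its share of sequence by a two-sided exact binomial test with an exact 95% Clopper-Pearson interval. The ratio of covered shares was given a 95% interval by resampling 100 kb windows 10000 times. Lengths and scores were compared by the difference of medians with two-sided permutation tests over clusters (100000 permutations for chromosome 4, 10000 for X). Overlap between replicates required at least 1 bp and was compared with 1000 circular shifts of 1 list along each arm, one-sided, with a smallest possible p of 0.001. Benjamini-Hochberg adjustment was applied within each family. These tests and intervals describe clusters or windows within lists. Fisher's exact tests set the numbers of clusters in the 2 replicate lists against each other. None of these tests measures variation between libraries of a group, for which an exact sign-flip test of 2 replicates cannot give a two-sided p below 0.5.

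The highest-scoring clusters named in the text were chosen by a rule fixed before the data were examined: clusters of the combined list touched by both replicate lists and ranked by score, the top 10 on chromosome 4, the top 10 on the other arms and the top 5 on X. Clusters named for their length were singled out after their values were seen. The gene table used here is of genome release 6 and coordinates were not converted between releases, so no gene was placed. The planned comparisons of genes and of fixed gene lists, and the values of roX1, roX2 and Pof, are therefore not analysed here. Alternatives fixed beforehand were each replicate's own list, a score filter at the median, a minimum length of 1000 bp, merging of clusters within 1000 bp, other overlap rules, and inclusion of the sequences outside the arms. The 2000 highest scores, a minimum length of 3000 bp, short shifts, an overlap without chromosome 4 and ranks from the highest-scoring overlapping cluster were added after the data were seen. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. On simulated lists with the real cluster lengths, a list copied from 30% of another was counted as 30%, which checks the counting only. Of 40 pairs of unrelated lists, 1 had p under 0.05. These were placed evenly at random and tested with fewer shifts, so they do not calibrate the test for regionally clustered lists. The median test, on simulated values, had p under 0.05 in 1 of 60 unchanged sets and in 20 of 20 sets raised 1.4 times. That rise is larger than the chromosome 4 length difference in any list as deposited.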

Results

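POF occupancy was profiled by ChIP-seq in Drosophila melanogaster larvae of the 3rd instar, with 2 ChIP libraries and 2 input libraries. The combined list of enriched clusters held 20574 clusters, of which 19605 lay on the 6 assembled arms. Replicate 1 alone gave 6433 clusters, 6120 of them on the arms, and replicate 2 alone gave 5786, 5668 of them on the arms. Clusters covered 30.96% of the arms in the combined list, 8.96% in replicate 1 and 10.7% in replicate 2. The shortest cluster measured 1001 bp in the combined list and 1301 bp in each replicate list.

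The first comparison asked how far POF clusters concentrate on chromosome 4, the small chromosome for which the protein is named. Chromosome 4 was densely covered in replicate 2 and sparsely covered in replicate 1. In replicate 2, 91 clusters covered 376857 bp, or 27.9% of chromosome 4, against 10.5% of the other arms, a ratio of 2.65 (95% interval over windows 2.37 to 3.10). In replicate 1, 28 clusters covered 53047 bp, or 3.92% of the chromosome, against 9.02% of the other arms, a ratio of 0.43 (0.23 to 0.60). The mean over both replicates was 15.9% ± 16.9 (SD, n = 2) for chromosome 4 and 9.78% ± 1.07 (SD, n = 2) for the other arms, so the difference between them lies within the spread between replicates. The mean score of the chromosome 4 clusters was 0.80 in replicate 2 and 0.68 in replicate 1, each on its own list's scale.

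**Figure D1:**
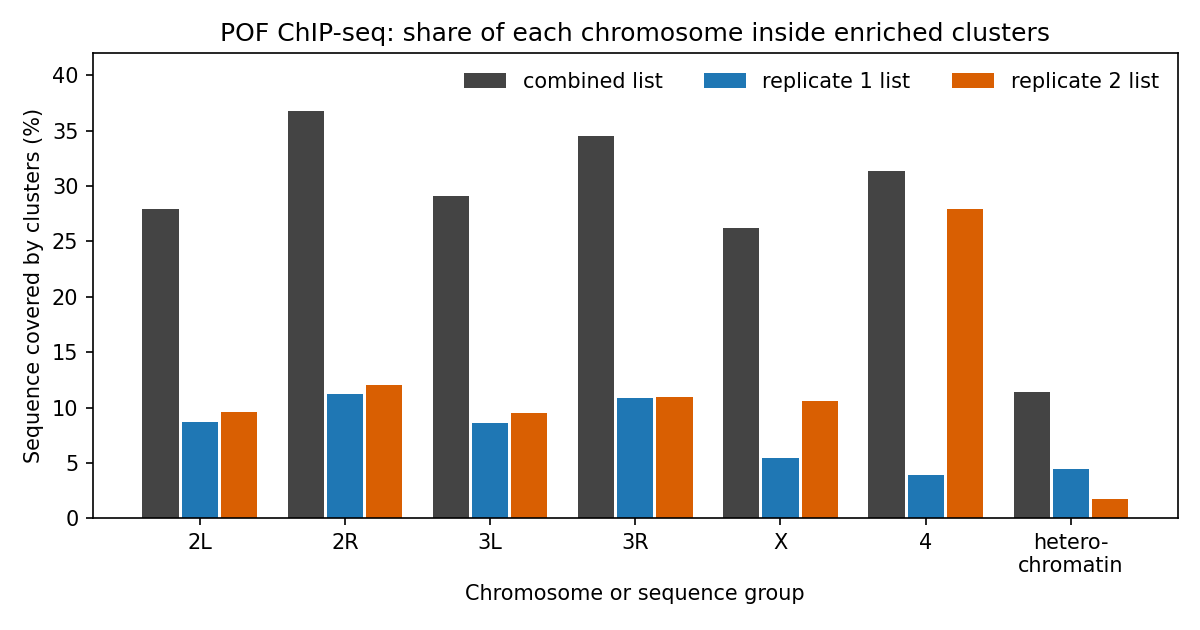
Share of each chromosome arm, and of the 6 heterochromatin sequences together, inside enriched clusters (y axis, percent), in the combined list and the list of each ChIP replicate (bars, 1 value each). The replicate lists lie close together on 2L, 2R, 3L and 3R, while chromosome 4 stands at 3.92% in replicate 1 and 27.9% in replicate 2.

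The combined list placed 157 clusters on chromosome 4, with 31.3% of its bases covered (423730 bp, mean score 0.53). The other arms were covered to 30.96% in that list, a ratio of 1.01 (95% interval 0.92 to 1.12). By number, chromosome 4 held 0.80% of the arm clusters of the combined list (exact 95% interval 0.68% to 0.94%), below its 1.12% of the sequence (two-sided exact binomial p = 8.7e-06). With heterochromatin and unplaced sequences included, the share was 0.76% against 0.80% of the sequence (exact binomial p = 0.58). On the arms alone, the share in replicate 1 was also below 1.12%, at 0.46% (exact binomial p = 3.8e-08). In replicate 2 it was above 1.12%, at 1.61% (exact binomial p = 0.001). The shares of the 2 replicate lists differed 3.51-fold (two-sided Fisher's exact p = 2.4e-10), a test that compares these libraries and not conditions. Among the 2000 highest scores on the arms, a count added after the data were seen, chromosome 4 took 53 clusters in the combined list (2.65%), 44 in replicate 2 (2.20%) and 10 in replicate 1 (0.50%). The combined list held 19605 arm clusters, replicate 2 held 5668 and replicate 1 held 6120. The filter is therefore stricter in the combined list, and its values are not on a like footing with those of the replicates. The ratio of covered shares in the combined list was 3.52 among these 2000 and 2.10 for clusters of at least 3000 bp, also added after the data were seen. Of the 53 in the combined list, 24 were touched only by replicate 2, 3 only by replicate 1, 14 by both and 12 by neither.

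Clusters on chromosome 4 were spread over nearly its whole length in replicate 2. In each of the 13 full windows of 100 kb, replicate 2 clusters covered between 15.0% and 35.9% of the sequence, with a mean of 29.0% ± 7.03 (SD over 13 windows). All 13 windows exceeded the median of the 1189 windows on the other arms, which was 9.11%. Of these other windows, 22 (1.85%) reached the chromosome 4 median of 31.9%. In replicate 1 the same 13 windows ranged from 0% to 10.5%, with a median of 2.76%, and 2 of them exceeded the median of the other arms. The last cluster of replicate 2 on chromosome 4 ended at position 1264921, whereas replicate 1 and the combined list had clusters up to 1342112 and 1342414.

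**Figure D2:**
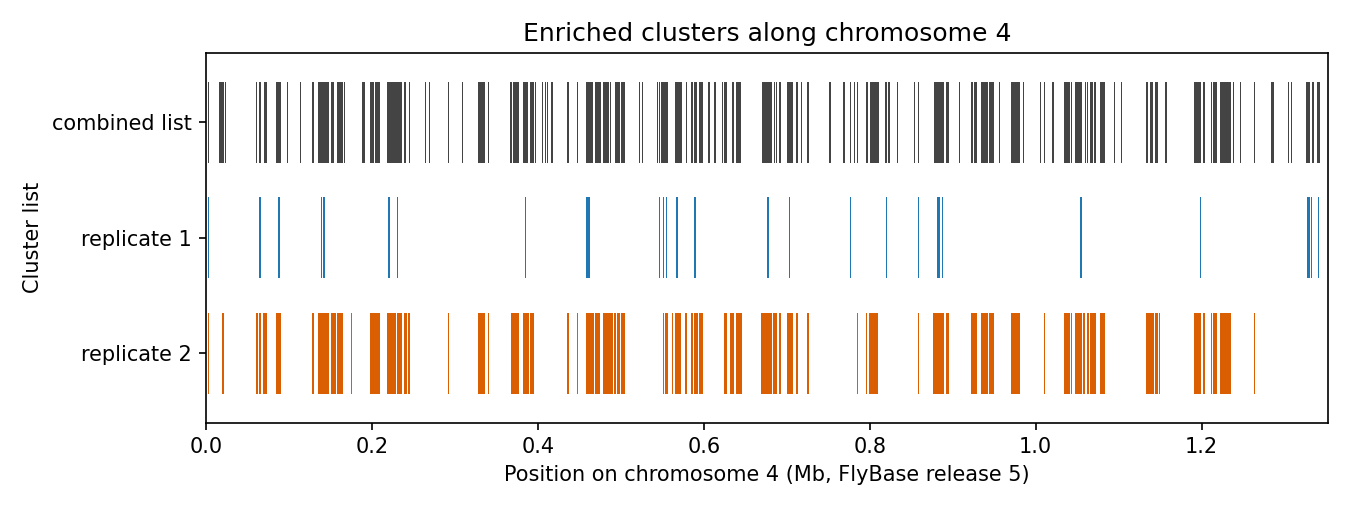
Map of the enriched clusters on chromosome 4 (x axis, position in Mb, FlyBase release 5), drawn to scale as blocks for the combined list, replicate 1 and replicate 2. The 91 clusters of replicate 2 form dense groups along the chromosome, while the 28 clusters of replicate 1 are scattered and shorter than those of replicate 2, with a median of 1822.5 bp against 2736 bp.

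The chromosome 4 clusters were longer than those elsewhere in all 3 lists. Their median length was 2736 bp in replicate 2, against 1985 bp on the other arms (permutation test over clusters, adjusted p = 0.00012). It was 1754 bp against 1527.5 bp in the combined list (permutation, adjusted p = 0.0039) and 1822.5 bp against 1597 bp in replicate 1 (permutation, adjusted p = 0.043, and an unadjusted p of 0.099 when clusters within 1000 bp were merged). Clusters of at least 3000 bp numbered 45 on chromosome 4 in replicate 2, 4.88% of all such arm clusters of that list, and 1 in replicate 1. Median scores on chromosome 4 did not pass the test in any list as deposited. The difference from the other arms was 0.01 in the combined list (permutation, adjusted p = 0.16), 0.03 in replicate 2 (permutation, adjusted p = 0.13) and -0.01 in replicate 1 (permutation, adjusted p = 0.52). Scores were spread more widely on chromosome 4 between the 10th and 90th percentiles. The 90th percentile was 0.87 against 0.56 in the combined list, 1.28 against 1.06 in replicate 2 and 1.00 against 0.77 in replicate 1, and the 10th percentile differed from that of the other arms by -0.06, -0.04 and -0.09. The highest score was lower on chromosome 4 in each list, at 1.81 against 3.398 in the combined list, 2.26 against 3.44 in replicate 2 and 1.68 against 4.25 in replicate 1. Chromosome 4 held far fewer clusters (157 against 19448 in the combined list). The maximum of a smaller set tends to be lower, so these maxima cannot show weaker sites on chromosome 4. After merging of clusters within 1000 bp, with the highest score kept, the median score differed by 0.25 in replicate 2 (permutation p = 1e-05) and by 0.034 in the combined list (permutation p = 7e-05), and the median lengths were 4241 bp against 2031 bp and 2245.5 bp against 1794 bp. In replicate 2, merging took chromosome 4 from 91 to 67 clusters and the other arms from 5577 to 4849. Keeping the highest score raises scores where clusters lie close, so the merged difference cannot be read as higher scores alone.

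The chromosome 4 cluster with the highest score among those in both replicate lists spanned positions 877822 to 889514 (11693 bp, score 1.81). In replicate 2 it corresponded to a single cluster of 12232 bp with a score of 2.26. In replicate 1 it was split into 3 clusters, of which the one with the largest overlap scored 0.72 and another, at 886688 to 888836, scored 1.68. The next in rank were 2 short clusters, at 63409 to 65494 (score 1.300) and at 229692 to 231841 (score 1.28). They were followed by 669958 to 679526 (0.95), 84514 to 89854 (0.93), 218163 to 224732 (0.92), 565591 to 571915 (0.89), 137012 to 144696 (0.89), 457468 to 465698 (0.86) and 588240 to 592230 (0.84). The same 10 regions ranked high within replicate 2, between the 90.1 and 99.6 percentiles of its scores (median 94.1). They were chosen for high combined scores. On chromosome 4, 81 combined clusters were touched by replicate 2 only and 6 by replicate 1 only. High ranks in replicate 2 are thus partly built into the choice. Within replicate 1, the cluster with the largest overlap in each region ranked between the 0.25 and 78.0 percentiles, with a median of 11.6. With the highest-scoring cluster in each region, a choice made after the data were seen, these ranks ran from the 0.25 to the 99.6 percentile, with a median of 20.4. The longest chromosome 4 cluster of replicate 2, at 134239 to 147770 (13532 bp, score 1.09), contained the region at 137012 and was singled out after its values were seen.

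Outside chromosome 4, the highest-scoring clusters found in both replicates lay on 3R, 3L, 2R, X and 2L. The leading cluster was on 3R at 9483608 to 9488081 (score 2.09), followed by 3L at 6597736 to 6601826 (2.04), 3R at 19684131 to 19686382 (2.01) and 2R at 13028670 to 13034457 (2.00). The remaining 6 were on X at 9978945 to 9981538 (1.99), 3R at 16646348 to 16649012 (1.99), 3R at 26631406 to 26635460 (1.95), 3L at 20518202 to 20520958 (1.83), 3L at 7126098 to 7128606 (1.77) and 2L at 18151192 to 18153555 (1.74). These 10 clusters were between 2252 and 5788 bp long. They ranked between the 99.55 and 99.93 percentiles of scores in replicate 2, and between the 64.8 and 99.6 percentiles in replicate 1, with a median of 98.2. All 10 scored at least 1.74, and 1 chromosome 4 cluster found in both replicates scored as high. The 10 regions named on chromosome 4 came from only 18 clusters found in both replicates, and those on the other arms from a far larger set. Neither ranks nor scores of these sets compare like with like.

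The X chromosome was the second comparison, because POF is known to bind sites near the roX genes, which encode non-coding RNAs of the male dosage compensation complex. X was covered less than the autosomal arms in replicate 1, at 5.46% against 9.85% (ratio 0.55, 95% interval over windows 0.50 to 0.62). In replicate 2 the values were 10.6% and 10.5% (ratio 1.01, 0.90 to 1.13), and in the combined list 26.2% and 32.1% (ratio 0.82, 0.76 to 0.87). The ratio was above 1 for combined clusters at or above the median score (1.39) and among the 2000 highest scores of the combined, replicate 1 and replicate 2 lists (2.12, 1.305 and 1.54). The 2000 highest scores are a smaller part of the combined list than of either replicate list. With all clusters, the covered lengths on X were 1225081 bp in replicate 1, 2379168 bp in replicate 2 and 5874837 bp in the combined list. The mean ratio over both replicates was 0.78 ± 0.32 (SD, n = 2), so it did not differ from 1 by more than the spread between replicates. Scores on X were higher than on the autosomal arms in all 3 lists. The median was 0.50 against 0.42 in the combined list, 0.74 against 0.62 in replicate 1 and 0.71 against 0.60 in replicate 2 (permutation tests over clusters, adjusted p = 0.0003 in each, from the smallest p that 10000 permutations can give).

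After X at 9978945, which is also the top cluster of X, the leading clusters on X found in both replicates were at 2624582 to 2628986 (score 1.68), 20125803 to 20129527 (1.67), 10241223 to 10243349 (1.63) and 16533515 to 16537602 (1.55). Their replicate 2 scores ranked between the 99.3 and 99.8 percentiles of that list, and their replicate 1 scores between the 85.9 and 98.6 percentiles. The longest cluster of the combined list was also on X, at 1764815 to 1785284 (20470 bp, score 0.96), and was touched by both replicate lists. It lay next to a cluster of 12719 bp at 1752087 to 1764805, which was touched by replicate 2 only. These last 2 were singled out after their values were seen.

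The replicate lists overlapped more than chance placement gave, on every arm, but shared a minority of their clusters. Of the 6120 arm clusters of replicate 1, 1699 (27.8%) were touched by a replicate 2 cluster, against a mean of 18.1% after circular shifts (one-sided permutation by shifts, p = 0.001, the smallest the shifts can give). Bases covered in both lists made up 11.2% of the bases covered in either, against 5.13% after shifts. On chromosome 4, 21 of 28 replicate 1 clusters (75%) were touched by replicate 2, against 37.8% after shifts (permutation by shifts, adjusted p = 0.002). In the other direction, 18 of the 91 replicate 2 clusters on chromosome 4 (19.8%) were touched by replicate 1, against 10.9% after shifts (permutation by shifts, adjusted p = 0.011). On X the share of replicate 1 clusters was 31.1% against 17.5%, and on the 4 autosomal arms it lay between 25.2% and 28.99%. Whether both lists were called against the same input library is not given in the sources used here.

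**Figure D3:**
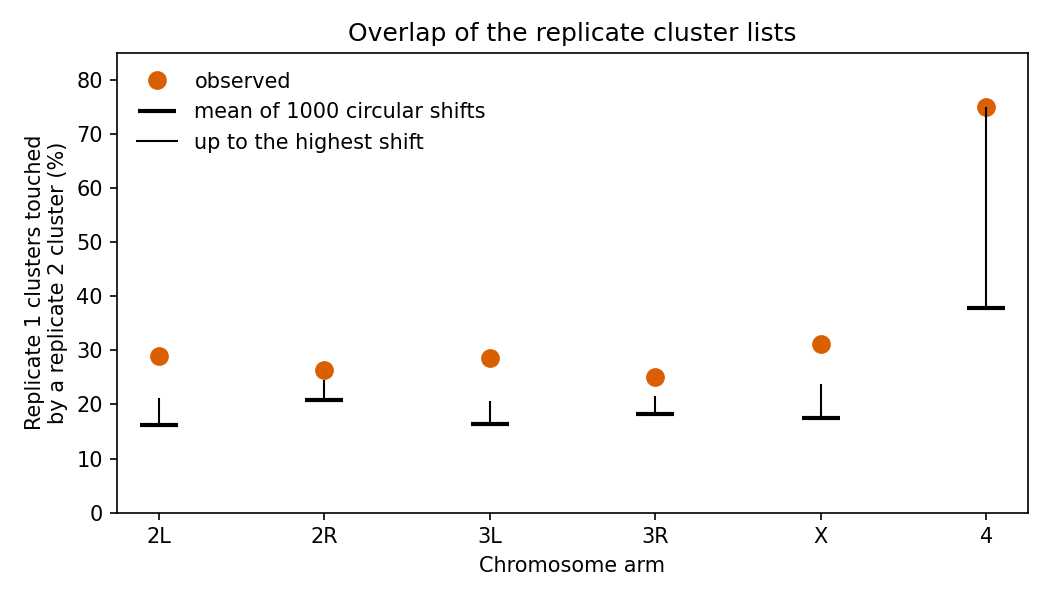
Percentage of replicate 1 clusters touched by at least 1 bp of a replicate 2 cluster on each arm (points), with the mean of 1000 circular shifts (horizontal marks) and a line up to the highest shift. The observed share exceeds the mean of the shifts on all 6 arms, with 75% against 37.8% on chromosome 4, where the highest shift reached the observed value.

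The scores of overlapping clusters were weakly related across clusters, which are not independent replicates. Over 1699 pairs, Spearman's rho was 0.13 and Pearson's r was 0.29 (permutation p = 1e-05 for each, the smallest the permutations can give). Within chromosome 4 rho was -0.08 over 21 pairs (permutation p = 0.74, adjusted p = 0.92), and within X it was -0.01 over 226 pairs (permutation p = 0.93, adjusted p = 0.93). Scores on X were higher in both replicate lists, so the pooled coefficients can partly reflect that difference between chromosomes. No coefficient within the autosomal arms is given. Covered shares of 100 kb windows had a rho of 0.41 and an r of 0.42 over the 1189 windows outside chromosome 4 (permutation p = 1e-05, adjusted p = 1.3e-05). Over the 13 windows of chromosome 4, rho was -0.17 and r was -0.02 (permutation p = 0.59, adjusted p = 0.59). Window coverage and the scores of overlapping clusters are different measures on different units, so their coefficients do not rank the agreement.

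The combined list touched nearly all clusters of the replicates by at least 1 bp and held many more. It touched 95.1% of the arm clusters of replicate 1 and 98.1% of those of replicate 2. No shares after shifts are given for these, and a list that covers 30.96% of the arms touches some clusters by placement alone. Of its 19605 arm clusters, 1681 (8.57%) were touched by both replicate lists, 4051 (20.7%) by replicate 1 only, 3871 (19.7%) by replicate 2 only, and 10002 (51.02%, exact 95% interval 50.3% to 51.7%) by neither. Of the 157 combined clusters on chromosome 4, 81 (51.6%) were touched by replicate 2 only and 6 (3.82%) by replicate 1 only, with 18 in both and 52 in neither. On X, 774 combined clusters (25.4%) were touched by replicate 2 only and 439 (14.4%) by replicate 1 only. Clusters touched by both had a median length of 3492 bp and a median score of 0.53, and those touched by neither 1234 bp and 0.43.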

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

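The tests of a general lack of clusters, of the score cut-off, of repeat-rich sequence, of weaker recovery and of X scores were chosen after the values were seen. Sequences outside the 6 arms, which the comparisons above do not use, held 969 clusters in the combined list, 313 in replicate 1 and 118 in replicate 2. They drew attention as clusters in sequence left out of the comparisons, and no control list sets a background for them. Of these, 613 combined clusters lay on the 6 heterochromatin sequences and 356 on the unplaced sequence U. The heterochromatin sequences were covered to 4.47% in replicate 1 and 1.70% in replicate 2 when pooled. The share was lower in replicate 2 on 2RHet (1.41% against 3.96%), 3LHet (2.01% against 5.91%) and 3RHet (1.50% against 4.93%). It was higher in replicate 2 on 2LHet (3.45% against 2.43%), XHet (4.09% against 0%) and YHet (0.45% against 0%), which held at most 5 clusters each in either list. On chromosome 4 the share in replicate 2 was 7.10 times that in replicate 1. Median scores on U were above those on the arms in every list, at 0.98 in the combined list, 0.95 in replicate 1 and 1.08 in replicate 2.

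The difference between the replicates on chromosome 4 is the pattern most in need of a second look. A general lack of clusters in replicate 1 is argued against, since the other arms were covered only 1.17 times as much in replicate 2, although X alone was covered 1.94 times as much and the autosomal arms 1.07 times. Among the 2000 highest scores of each list, chromosome 4 held 4.4 times as many clusters in replicate 2 (44 against 10, Fisher's exact p = 2.9e-06). This argues against a different cut-off on the ranked scores alone. The shares in the full lists already differed 3.51-fold, and the caller's threshold is not given. The count therefore cannot decide on a cut-off on another measure, or on sites that were never called in replicate 1. Better recovery of repeat-rich sequence in general is argued against by the heterochromatin sequences, at 0.38 times the replicate 1 share when pooled. On few clusters, however, 2LHet, XHet and YHet went the other way. A hypothesis that stays open is weaker recovery of the same chromosome 4 sites in replicate 1: its few clusters there lay on those of replicate 2 at 1.99 times the rate after shifts (permutation by shifts, p = 0.002), as this explanation needs, although the other arms also overlapped above shifts. The highest shift, however, also reached the observed 75%. Within chromosome 4 the replicates were not correlated in window coverage (rho -0.17, 13 windows) or in scores (rho -0.08, 21 pairs). The descriptions of ChIP replicate 2 and input replicate 1 conflict with their titles, and the lists cannot tell whether that bears on this difference. By their titles both ChIP libraries belong to 1 group, so no biological explanation was tested.

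The higher scores on X, present in all 3 lists, were seen at the 10th percentile, the median and the 90th percentile. The highest score was not higher on X in replicate 2 (2.62 against 3.44) or in the combined list (3.398 on both). In replicate 1 it was higher on X (4.25 against 2.36). A maximum is a single cluster, and X held fewer clusters than the autosomal arms. The maxima also differ in direction between lists, so they cannot decide how far the pattern of higher scores on X reaches. Strong sites on X alone are argued against, since the shift of the 90th percentile was at most 1.64 times that of the 10th. A higher score needed for a call on X would shift the 10th percentile too. That percentile was shifted by at least 0.72 of the median shift in each list. Such a requirement alone would also leave fewer calls on X. X was covered less in replicate 1 (5.46% against 9.85%) and in the combined list (26.2% against 32.1%). In replicate 2 it was not (10.6% against 10.5%), so this explanation stays open and unsettled. A single X in males gives fewer reads and may raise the score needed for a call. Read depth and the sex of the larvae are unknown, so a broad gain of POF signal on X stays open as well.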

How the results depend on the processing

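No paired analysis was possible because the input libraries, which share the numbers 1 and 2 with the ChIP libraries, have no list analysed here. Of 42 values under alternative settings, 28 kept their direction and their side of the threshold or moved less than the replicate spread. For the covered ratio of chromosome 4 that spread was wide (SD 1.56, n = 2). Ratios from 0.40 to 2.10 therefore counted as unmoved from 1.01, and the count of 28 does not show that this ratio was stable. The chromosome 4 share of clusters, 0.80% and below its share of sequence, ranged from 0.46% to 1.61% over the replicate lists, and turned to above it without replicate 1 (1.61%) and among the 2000 highest scores (2.65% in the combined list, 2.20% in replicate 2). With all other sequences included it was 0.76% against 0.80% of sequence (exact binomial p = 0.58). The covered ratio of chromosome 4, 1.01, ranged from 0.43 to 2.65 over the replicate lists and was 3.52, 4.22 and 0.40 among the 2000 highest scores of the combined, replicate 2 and replicate 1 lists and 2.10 for combined clusters of at least 3000 bp. The X ratio, 0.82, was 1.39 for clusters at or above the median score and 2.12, 1.305 and 1.54 among the 2000 highest scores of the combined, replicate 1 and replicate 2 lists, a filter that favours X because X scores are higher. Combined clusters in neither replicate list made up 54.5% under an overlap of at least 50%. The score difference on chromosome 4, 0.010, ranged from -0.014 without replicate 2 to 0.035 without replicate 1, and passed the test when clusters within 1000 bp were merged (0.034, permutation p = 7e-05). Merging also moved it to 0.25 in replicate 2 (permutation p = 1e-05), and moved the length difference from 226.5 to 451.5 bp in the combined list and from 751 to 2210 bp in replicate 2. A merged cluster keeps the highest score, so close spacing of clusters alone can raise merged scores. The cause was not tested except where stated. Replicate overlap and score correlation kept their calls under all 9 settings run. The score correlations within chromosome 4 (rho -0.08) and within X (rho -0.01), which did not pass the test, are not among these 9. The minimum length of 1000 bp, which is among the 9 settings and among the 28 values, removed no cluster and tests nothing. Gene comparisons were not run. Unknown depth limits every difference between the lists.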

Other observations

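Coverage differed between windows of the large arms. In the combined list the most densely covered 1 Mb windows were on 2R at 20000001 to 21000000 (52.0%) and at 19000001 to 20000000 (51.1%), and on X at 1000001 to 2000000 (50.6%). In these 3 windows replicate 1 covered 17.4%, 16.2% and 12.2%, and replicate 2 covered 16.6%, 19.7% and 20.8%. The least covered full window was on 2L at 17000001 to 18000000, with 13.1% in the combined list, 4.48% in replicate 1 and 2.89% in replicate 2. The single region called depleted in the combined list lay on 2L at 13370022 to 13371374, with a score of -0.036.

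A further pattern is that 10002 of the combined arm clusters were in neither replicate list; both tests of it were chosen before their results were seen. Of these, 58.2% (5821) were shorter than 1301 bp, the shortest cluster of either replicate list, so a shorter minimum length in the combined list may account for many of them. Over all combined arm clusters, the first quartile of length was 1188 bp and the median 1529 bp. Short clusters were thus common in the whole list, and this share alone cannot say how many the minimum length accounts for. The median score of clusters in neither list was 0.10 lower than that of clusters in both lists (difference -0.10, permutation p = 0.001). Clusters called in each replicate list tend to score higher in a list for the same libraries. This difference is thus partly built into the grouping and cannot show weaker sites. The median of 0.43 in neither list was close to those of clusters touched by replicate 1 only (0.43) or by replicate 2 only (0.42). Low scores therefore do not set the clusters in neither list apart from those. How the combined list was made is not given in the sources used here, which leaves a pooled call on more reads open.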
